A study of Mus musculus with 9 samples.

How the data were processed

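Mouse liver RNA was sequenced from libraries made with a stranded mRNA kit, per the labels' protocols. The submitters' processing notes name the aligner STAR 2.5.2a and the genome build GRCm38. The counting tool and the gene annotation are not given in the sources used here. The deposited table holds Ensembl gene identifiers in rows and 9 columns of values.

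Each column heading was searched for in every label of every sample and in the text of the series, and none occurred there. Columns were not assigned by their order or by the expression values in them, since neither is a label. The values were looked at only to see the form of the table, and no result was computed from them. The tests of DIO-NASH against Lean chow that were fixed before the data were examined (a test per gene, tests of gene lists and comparisons of list scores) were not run.

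The gene identifiers were matched, without their version, to GENCODE M21, an annotation of GRCm38, with Python 3.11.15. It may not be the annotation that the submitters counted with. Coordinates are 1-based and come from GENCODE M21. The genes of 45 lists, written from textbook knowledge before the data were examined, were matched by symbol, by older symbol or by synonym in a RefSeq table of the same build.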

Results

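The study profiled liver RNA from mice on a diet that produces non-alcoholic steatohepatitis (DIO-NASH, fed the AMLN diet) and from lean mice on rodent chow. The AMLN diet is rich in fat, fructose and cholesterol. The labels name 5 Lean chow and 4 DIO-NASH samples, each after 36 weeks on diet, and the comparison that the design implies is DIO-NASH against Lean chow. No expression level, fold change or test is given for it. The 9 columns of the deposited gene table are headed by numbers that occur in no sample's labels, so no column was assigned to a sample or to a diet group, and no result was computed from the values in the columns. Depth per sample is not given for the same reason. What follows describes which genes the table covers, and holds no statement on how any gene differed between the diets.

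The table has 22025 distinct Ensembl gene identifiers, of which 21948 were found in the GENCODE M21 annotation of GRCm38. Of the identifiers found, 21826 were annotated as protein-coding, which is 99.4% of them. Those genes made up 99.1% of the 22028 protein-coding genes in that annotation. The table also covers 13 genes of the mitochondrial chromosome. Long intergenic and antisense RNA genes accounted for only 36 identifiers.

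Nearly all genes of the lists were covered, meaning only that the table has a row for them. Whether they were detected in these livers was not examined. The share covered was 99.0% over list genes of every class, including some not annotated as protein-coding. For the protein-coding genes of the annotation alone it was 99.1%. These shares are over unlike sets of genes, so their closeness has no meaning. Since nearly all protein-coding genes have a row, high coverage is not particular to these lists. Of 859 distinct genes in 45 lists, 850 had an identifier in the table. Most lists were for liver cell types, metabolism, inflammation, fibrosis and stress. Others held erythroid, adipocyte and pancreatic acinar markers, or cell cycle, circadian clock, immediate early and sex-biased genes. Of the 45 lists, 40 were covered in full. Among them were collagens (17 genes), cholesterol biosynthesis (24 genes) and bile acid synthesis and transport (23 genes). The lists of resident Kupffer cell markers (16 genes) and lipid-associated macrophage markers (20 genes) were others. Col1a1, which encodes a chain of fibrillar type I collagen, lies on chromosome 11 from 94936224 to 94953042 in GRCm38. Cyp7a1, the rate-limiting enzyme of bile acid synthesis from cholesterol, lies on chromosome 4 from 6265612 to 6275633. Trem2, a macrophage receptor for lipids, lies on chromosome 17 from 48346401 to 48354147, and the Kupffer cell lectin gene Clec4f lies on chromosome 6 from 83644542 to 83656187. The annotation classes each of these genes as protein-coding. These genes were chosen as examples of their lists with no expression value in view.

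The list of B and plasma cell markers was the least completely covered, with 10 of 15 genes. The immunoglobulin constant region genes Ighm, Ighd, Igkc, Iglc1 and Iglc2 had no identifier in the table. The T cell receptor constant region gene Trac, the interferon-stimulated gene Mx2 and the long non-coding RNA H19 had none either. The annotation classes Mx2 as a polymorphic pseudogene and H19 as a long intergenic RNA, not as protein-coding. The symbol of the erythroid gene Ahsp was matched to no identifier, so its presence in the table was not checked. The immunoglobulin genes and Trac belong to gene classes of the annotation with no member among the matched identifiers: 0 of 13 immunoglobulin constant region genes and 0 of 8 T cell receptor constant region genes were matched. The same held for the variable region genes, with 0 of 218 for immunoglobulins and 0 of 144 for T cell receptors. The lower coverage of the B and plasma cell list thus follows a whole gene class with no matched identifier in the table.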

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

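The count of protein-coding genes in the table was taken from GENCODE M21 (21826) and, as an alternative chosen after seeing the data, from a RefSeq table of the same build matched by symbol. That table held the symbols of 20868 of the identifiers and classed 20440 of these as protein-coding, so the lower count also reflects identifiers whose symbol was not matched. No normalization, filter or test was run for the comparison of DIO-NASH against Lean chow, since no column was assigned to a sample. Fits with a replicate block or with each library left out were not run either. No paired analysis was possible because the columns carry no replicate number. The replicate numbers in the labels are shared by mice on different diets and are tied there to no litter, batch or day. Nothing here bears on depth or on the spread between animals.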
